A study of Mus musculus with 5 samples.

How the data were processed

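Total RNA from non-tumour colon of 5 mice was converted to biotin-labelled cRNA, hybridised to MEEBO mouse oligonucleotide arrays and stained with a streptavidin-coupled fluorescent dye, per the labels' protocols. Each sample had 1 array in 1 colour. Groups were taken from the sample titles: 2 villin-TLR4 mice and 3 WT littermates. The labels give each sample a number, a sex and an age but do not state in words that each came from a separate animal. The labels also do not say that a number pairs animals across groups, so the numbers were not used as pairs. Limma's p-values for single probes measure the spread between these samples. Those of its list test camera with the preset correlation compare a list's genes with all other genes. Genes and not samples are the units there.

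Per the file headers, the deposited array files hold spot intensity read with GenePix Pro 4.1.1.4, with a local background, no normalization and the spot marks of the software (found, not found, bad). The deposited table of the whole series holds, for 15308 probes, a ratio on a linear scale. Set against the scanner values, the log2 differences between its columns and those of background-subtracted intensity matched with a residual SD of 0.000749 for the villin-TLR4 arrays and 0.0106 for WT replicate 1 against villin-TLR4 replicate 1, so the values are background-subtracted intensity scaled by 1 factor per array and divided by 1 factor per probe. Their direction follows the scanner values. How these factors were chosen is not given in the sources used here. The medians of its columns were 0.981, 1.06, 1.18, 0.980 and 0.991 in the order villin-TLR4 replicates 1 and 2 and WT replicates 1 to 3, and 281, 879, 6308, 382 and 746 values were missing.

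The analysis used R 4.3.3 and limma 3.58.1. Background was corrected with normexp (offset 50) on the median foreground and local background, over all 38880 spots. The 4568 spots outside the gene probe classes were then left out, as were single values of spots marked bad (2, 0, 1046, 4 and 1 gene spots per array). The remaining values were quantile normalized between arrays as log2 intensity. A probe was kept when the scanner software marked it found on at least 2 arrays, which left 18770 of 34312 gene probes; 586 of these lacked a value on at least 1 array. Saturated spots (at most 17 gene probes per array) were kept. The share of gene probes found was 50.2% and 46.8% on the villin-TLR4 arrays and 38.1%, 55.0% and 55.8% on the WT arrays. No pair of arrays held the same values. Probes were named by RefSeq accession, without version, through a gene table of the GRCm38.p6 assembly. It matched 22933 gene probes (66.8%; 94.4% of the 24283 with a RefSeq mRNA accession) to 15596 genes, and 6093 gene probes had no accession in the files. The kept probes named 10540 genes, 3041 with several kept probes; the probe with the highest mean over all arrays then stood for the gene. No coordinates were used. Of the genes to be named always, Duox2, Muc2, Ceacam20 and Mki67 had no matched probe and were not analysed here.

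Villin-TLR4 was compared with WT by lmFit and eBayes over all 5 arrays with no covariate, two-sided, with Benjamini-Hochberg adjustment over probes and calls at an adjusted p below 0.05. DSS strength was fixed by genotype and could enter no model. For a probe marked found on no array of a group, the fold is a bound. It sets the mean of the bright group against a mean over the dim group's arrays. Each of these arrays gave the higher of the lowest signal among probes found there and the probe's own. Such a bound concerns the group means and does not allow for the spread between arrays. For Cela2a, Pnlip and Apoc3 the probe's own signal was the higher. Their folds are therefore those of the group means and not lower limits. The 49 gene lists were tested with camera (preset correlation 0.01, 1 probe per gene with a value on every array, 10232 genes), where at least 5 genes were measured; the Y-linked list was left out of this family. Medians of lists in the results cover all measured members, while medians under the alternatives cover the genes that camera could use, so the same list can differ slightly between them. Counts of members adjusted over the list alone used limma's p over that list's measured members. Non-overlap of a gene means that both villin-TLR4 values lay on one side of every measured WT value.

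The genes named were fixed by rule before the data were examined: 16 genes given always; the called genes with the largest change, filled to 5 in each direction with the smallest p among genes whose groups did not overlap; and, for each called list, the 4 members with the smallest p in its direction, or 2 for a list not called. Some genes that the rule selects are not reported here. Genes outside this rule are marked in the text where they appear. The fits were tested on simulated data with the means and spread of these arrays (18184 probes, 68, 66 and 66 of them changed by a log2 of 1, 2 and 3) and 1 list of 48 shifted by a log2 of 1, which was called with 0 others. The simulated genes were independent of each other, so this does not show how often lists of correlated genes are called by chance. Each simulated probe had the same SD on every array, whereas the real arrays differed in spread.

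The alternatives fixed before the data were examined were no background correction, plain subtraction, a normexp offset of 16, cyclic loess, median centring, the deposited table, no filter on dim probes, probes found on all 5 arrays, arrayWeights, eBayes with trend and robust, the replicate number or the scan day as a block, each array left out in turn, the estimated correlation, fry, the mean of a gene's probes, and an unadjusted p below 0.05 with a fold of at least 1.5. The list test without WT replicate 1 with an estimated correlation and a second way of computing array weights were added after the data were seen. The deposited table served as an alternative alone, since scanner values were at hand.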

Results

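Gene expression was measured in pieces of mouse colon that had formed no tumour, taken after a course of colitis-associated carcinogenesis. C57Bl6 mice, 10 weeks old at the start, received 7.4 mg/kg of AOM (azoxymethane, a carcinogen), then DSS (dextran sulfate sodium, which injures the colon epithelium) for 7 days from day 7 and again for 5 days, and were killed on day 56. The groups were 2 samples of villin-TLR4 mice (replicate 1 female and replicate 2 male) and 3 of female WT littermates. TLR4 is the receptor for bacterial lipopolysaccharide, and villin is an epithelial gene whose promoter is commonly used to express transgenes in the gut; the labels do not describe the construct. DSS was given at 1.5% to the villin-TLR4 mice and at 3% to the WT mice, so that genotype and DSS strength cannot be separated in any value below.

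Each RNA was hybridised to 1 one-colour array with 34312 gene probes. The scanner software marked 17236 and 16042 probes as found on the villin-TLR4 arrays, and 13086, 18865 and 19150 on the WT arrays. This mark is not a test of signal against background. The median signal over background was 50 and 31 on the villin-TLR4 arrays and 29, 49 and 65 on the WT arrays, and the number of arrays limits the precision of every value. WT replicate 1 stood apart: its Pearson correlation with the other arrays lay between 0.887 and 0.897, against 0.954 to 0.977 for the other 6 pairs. Each correlation used those of the 18770 kept probes that had a value on both arrays. Probes are not independent replicates. The first principal component (60.6% of the variance) separated WT replicate 1 from the other 4 arrays, and the second (19.8%) ran from WT replicate 2 at -34.8 and WT replicate 3 at -19.7 to the villin-TLR4 arrays at 21.8 and 32.5, with WT replicate 1 at 0.31. The Y-linked genes Ddx3y and Eif2s3y had log2 signals of 8.76 and 9.10 on the array of the male mouse and at most 6.13 and 6.24 on the arrays of the females. Their mean on the male array exceeded the highest female mean by 2.74.

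The comparison of villin-TLR4 with WT colon asked how tissue outside tumours differed between the genotypes. Genes of sterol and lipid synthesis were higher in villin-TLR4 colon as a group, with a median log2 difference of 0.54 and all 21 measured members above 0. The list was called with the preset correlation between genes and not with an estimated one (adjusted p = 0.304). Genes of hypoxia and glycolysis were also higher, with a median of 0.44 and 20 of 23 members above 0, again not called with an estimated correlation (adjusted p = 0.304). The estimated correlations were 0.0079 for sterol and lipid synthesis and -0.011 for hypoxia and glycolysis, no higher than the preset 0.01. A higher correlation is therefore not what ended these 2 calls. The 2 settings also differ in degrees of freedom. With an estimated correlation and all arrays, camera takes the 3 residual degrees of freedom of the fit. With the preset correlation it takes a number set by the genes. The few arrays thus limit every list test with an estimated correlation. Markers of exocrine pancreas were lower, with a median of -2.74 (-1.22 without WT replicate 3) and all 11 members below 0, and so were markers of small intestine and Paneth cells, with a median of -0.72 over 13 members. Neither of these 2 lists was called with an estimated correlation (adjusted p = 0.859 and 0.6005), which was 0.78 for exocrine pancreas and 0.095 for small intestine and Paneth markers. No single gene passed the test over all genes. Differences are log2 villin-TLR4 minus WT ± SE throughout, with n = 2 and n = 3.

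By limma, 0 of 18770 probes were called higher and 0 lower at an adjusted p below 0.05, and the smallest adjusted p was 0.882. At an unadjusted p below 0.05 there were 805 probes (426 higher, 379 lower), where chance alone gives about 938; the number was 261 without villin-TLR4 replicate 1, 242 without villin-TLR4 replicate 2 and 2063 without WT replicate 1. Without WT replicate 1 the smallest adjusted p was 0.0565, and without WT replicate 2 a single probe, of Apoa1, was called. Groups did not overlap for 1407 of 10540 genes in the higher direction (13.3%) and for 1365 in the lower (13.0%), where chance gives 10% each way. A comparison of 2 with 3 arrays allows no two-sided exact permutation p below 0.2 for a single gene. In simulated data, limma recovered 0 of 68 probes changed by a log2 of 1, 23 of 66 (34.8%) changed by 2 and 45 of 66 (68.2%) changed by 3. There each probe had the spread of the fit, equal on every array, so the unequal spread of the real arrays was not covered.

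Among genes whose groups did not overlap, those with the smallest p in the higher direction were Atf3, a stress-induced transcription factor (2.27 ± 0.32, 4.82-fold), Slc5a8, a short-chain fatty acid transporter of colonocytes (1.75 ± 0.30), Lzts3 (1.91 ± 0.33), Lpcat1, an enzyme of phosphatidylcholine remodelling (1.26 ± 0.22), and the linker histone H1f2 (1.25 ± 0.23). In the lower direction they were the apolipoproteins Apoa4 (-2.998 ± 0.38, 7.99-fold lower) and Apoa1 (-4.69 ± 0.63, 25.8-fold lower), the AP-1 subunit Fosl1 (-2.67 ± 0.43), the hyaluronan receptor Cd44 (-1.42 ± 0.23) and the cytoplasmic actin Actg1 (-1.43 ± 0.24). The 7 kept probes of Cd44 ranged from -1.42 to -0.21. The Actg1 value is uncertain, since a probe of an actin gene can also bind the transcripts of its paralogues. For each of these 10 genes limma's adjusted p was 0.882, so that these are values and not called changes. Apoa1 was marked found on 1 of the villin-TLR4 arrays.

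**Figure D1:**
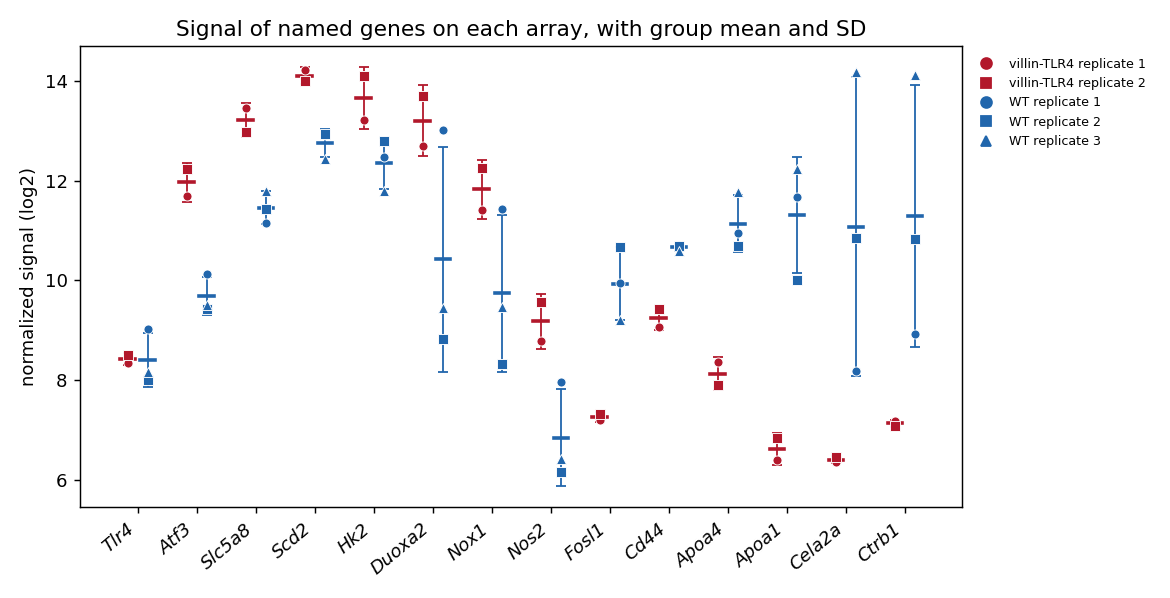
Normalized log2 signal (vertical axis) of 14 genes (horizontal axis) on each array, villin-TLR4 in red and WT in blue, with the marker shape giving the replicate, thick lines the group means and thin bars the SD. Atf3, Slc5a8, Scd2 and Hk2 lay above every WT array on both villin-TLR4 arrays and Apoa1, Apoa4, Fosl1 and Cd44 below; for Duoxa2 and Nox1, WT replicate 1 lay between the villin-TLR4 arrays, and Cela2a and Ctrb1 spread widely over the WT arrays.

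The receptor and its partners showed no called difference. Tlr4 differed by 0.02 ± 0.35 at the brighter of its 2 kept probes; nothing in the labels says whether these probes bind a transcript of the transgene, so they check nothing about it. Cd4 was not marked found on either villin-TLR4 array and differed by -0.09 ± 0.23, with groups that overlapped. Without villin-TLR4 replicate 1 its difference was 0.066. Ly96 (MD-2, the co-receptor) differed by -0.46 ± 0.52 and Cd14 by 0.50 ± 0.67. Among genes of epithelial oxidant defence, Duoxa2, the maturation factor of the oxidase Duox2, differed by 2.78 ± 1.18 and Nox1 by 2.09 ± 0.84 (1.15 at its other kept probe and 1.38 without WT replicate 2). Nos2, the inducible nitric oxide synthase, differed by 2.33 ± 0.57. It was marked found on both villin-TLR4 arrays and on 1 of 3 WT arrays. For the inflammatory and antimicrobial genes the values were -0.60 ± 0.74 for Lcn2, 0.52 ± 1.80 for Reg3b, 1.10 ± 1.95 for Reg3g and 0.20 ± 1.43 for Il1b. The stem cell gene Lgr5, marked found on only 1 villin-TLR4 and 1 WT array, differed by -0.03 ± 0.23. Limma's adjusted p ranged from 0.882 to 0.990 over these 12 genes. Reg3b, Reg3g and Il1b were brightest on WT replicate 1, where their log2 signals were 13.3, 14.0 and 12.5, against at most 8.19, 8.08 and 7.94 on WT replicates 2 and 3. Reg3b and Reg3g also differed between the villin-TLR4 arrays, with 8.57 and 11.9 for Reg3b and 9.65 and 12.2 for Reg3g. With each array left out in turn the values ranged from -0.18 to 0.34 for Tlr4, -0.77 to 0.09 for Ly96, 0.10 to 1.20 for Cd14, -1.03 to 0.18 for Lcn2, -1.16 to 2.32 for Reg3b, -0.17 to 3.20 for Reg3g, -0.69 to 1.79 for Il1b and -0.22 to 0.15 for Lgr5; without WT replicate 1 Ly96 and Lcn2 turned higher.

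Of 49 gene lists fixed before the data were examined, 48 had enough measured genes for camera, limma's test of a list against all other genes. With the preset correlation between genes, 11 lists were called, 6 higher and 5 lower. With an estimated correlation 0 were called (smallest adjusted p 0.304), and fry, which asks whether a list's genes move on balance one way, called 0 (smallest adjusted p 0.0784). Every one of the other 9 splits of the 5 arrays into 2 and 3 called at least 11 lists too, and the highest called 25. Without WT replicate 1 there were also 11 called lists, of which 8 were called in the same direction with all arrays; without villin-TLR4 replicate 2 there were 17 and without WT replicate 3 there were 20.

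Sterol and lipid synthesis was called higher at an adjusted p of 5.64e-07 (adjusted p = 0.304 with an estimated correlation). Groups did not overlap for 11 of its 21 members, all in the higher direction. No member passed over all genes; 2 passed adjusted over the list alone, among them the desaturase Scd2 (1.34 ± 0.26). The latter count was 12 without WT replicate 1 and 0 without villin-TLR4 replicate 1, villin-TLR4 replicate 2 or WT replicate 3. The mevalonate-pathway enzyme Hmgcs1 differed by 0.83 ± 0.28. Hypoxia and glycolysis was called higher at an adjusted p of 1.45e-05 (adjusted p = 0.304 with an estimated correlation). Of its 23 members, 7 had groups that did not overlap and 0 passed over all genes or adjusted over the list alone. Without WT replicate 1, 7 passed over the list alone. The values were 1.30 ± 0.40 for hexokinase Hk2 (0.86 without villin-TLR4 replicate 2), 0.97 ± 0.29 for phosphofructokinase Pfkl, 0.83 ± 0.24 for the angiogenic factor Vegfa and 0.81 ± 0.26 for the mTORC1 inhibitor Ddit4.

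Exocrine pancreas markers were called lower at an adjusted p of 5.64e-07 (adjusted p = 0.859 with an estimated correlation), with 9 of 11 members lower on both villin-TLR4 arrays than on every WT array. The elastase Cela2a and the lipase Pnlip were not marked found on either villin-TLR4 array. Their means lay 25.3-fold and 9.17-fold lower there. These folds were 8.63 and 3.32 without WT replicate 3, and 68.5 and 21.7 without WT replicate 1. The chymotrypsinogen Ctrb1 differed by -4.15 ± 1.33 and Cela3b by -1.88 ± 0.77 (-2.74 and -1.04 without WT replicate 3). The WT arrays themselves spread widely: 10 of the 11 members were brightest on WT replicate 3, where the list's median lay 3.31 above WT replicate 2 and 5.15 above WT replicate 1. Without WT replicate 3 the list's median was -1.22. Of the 11 members, 0 passed over all genes or adjusted over the list alone. The latter count was 9 without WT replicate 1, 1 without WT replicate 2 and 2 without WT replicate 3.

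Small intestine and Paneth markers were called lower at an adjusted p of 1.26e-05 (adjusted p = 0.6005 with an estimated correlation). Of 13 members, 0 passed over all genes and 3 passed adjusted over the list alone: Apoa1, Apoa4 and the Paneth cell lysozyme Lyz1 (-1.63 ± 0.46, and -0.95 at its other kept probe); 5 did without WT replicate 2. Apoc3 differed by -1.41 ± 0.44 (2.66-fold lower) and was not marked found on either villin-TLR4 array. Stratified squamous epithelium markers were called lower at an adjusted p of 1.77e-04 (adjusted p = 0.859 with an estimated correlation), with a median of -0.82 over 12 members and no member passing either way (2 over the list alone without WT replicate 1 and 6 without WT replicate 3). The keratins Krt1 and Krt13 differed by -0.88 ± 0.24 and -1.79 ± 0.68, the transglutaminase Tgm1 by -1.03 ± 0.37 and Dmkn by -1.67 ± 0.70. On WT replicate 1 this list's median lay 1.21 above the mean of the other WT arrays, and the list's median was -0.53 without that array and -1.28 without WT replicate 3.

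Interferon-stimulated genes were called lower at an adjusted p of 1.51e-03 (adjusted p = 0.859 with an estimated correlation), with a median of -0.55 and 21 of 25 members below 0, of which 0 passed over all genes or adjusted over the list alone (2 over the list alone without WT replicate 3). Ifi27l2a differed by -1.60 ± 0.46, Isg20 by -0.89 ± 0.30, and the guanylate-binding proteins Gbp2 and Gbp3 by -1.46 ± 0.51 and -1.08 ± 0.54. Gbp3 was -0.51 without villin-TLR4 replicate 1, -1.64 without villin-TLR4 replicate 2 and -0.67 without WT replicate 2. The call ended without villin-TLR4 replicate 1 (adjusted p = 0.916) and without WT replicate 2 (adjusted p = 0.768), where the medians were 0.0014 and -0.027. The median was -1.04 without villin-TLR4 replicate 2 and -0.85 without WT replicate 3. Genes of fetal-like and repair epithelium were called lower at an adjusted p of 7.33e-03 (adjusted p = 0.859 with an estimated correlation), with a median of -0.48 over 18 members. Tnfrsf12a, the receptor for TWEAK, differed by -2.25 ± 0.56, Anxa1 by -1.12 ± 0.49, Ly6c1 by -0.86 ± 0.36 (Anxa1 -0.705 and Ly6c1 -0.56 without WT replicate 1) and Clu by -0.63 ± 0.25, and 0 members passed either way (over the list alone, 3 lower and 1 higher without WT replicate 1 and 2 lower without WT replicate 3). This call ended without villin-TLR4 replicate 1 (adjusted p = 0.144) and without WT replicate 1 (adjusted p = 0.420), where the medians were -0.30 and -0.13. The median was -0.73 without WT replicate 3.

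The other lists called higher were small shifts or small lists, each with 0 members passing over all genes or adjusted over the list alone, and for each adjusted p = 0.859 with an estimated correlation. Erythrocyte markers had a median of 1.25 over 6 members (adjusted p = 0.0213), with values of 1.97 ± 0.81 for the globin Hba-a1 and 1.71 ± 0.66 for Alas2, the heme-synthesis enzyme of erythroid cells. Without villin-TLR4 replicate 1 these were 1.28 and 0.87, and Hba-a1 was 1.24 without WT replicate 3. Crypt-base stem cell markers had a median of 0.39 over 14 members (adjusted p = 0.0247), with 0.53 ± 0.26 for Axin2 and 0.51 ± 0.27 for Ascl2 (-0.10 at its other kept probe). Without villin-TLR4 replicate 1 these were 0.30 and 0.26. Circadian clock genes had a median of 0.36 over 17 members (adjusted p = 0.0247), with 1.401 ± 0.38 for Nr1d1 (0.14 at its other kept probe and 0.79 without villin-TLR4 replicate 2), 1.15 ± 0.32 for Npas2 (0.56 at its other) and 1.03 ± 0.37 for Per1. Plasma cell markers had a median of 0.34 over 13 members (adjusted p = 0.0434), with 1.56 ± 0.47 for Mzb1 and 0.70 ± 0.42 for the immunoglobulin joining chain Jchain (0.29 without WT replicate 2). Without WT replicate 1, 4 erythrocyte members passed higher over the list alone and 1 lower, Car1 (-1.52). Car1 is also on the absorptive colonocyte list and was chosen after its value was seen. In the same way 1 clock gene passed without WT replicate 1 and 1 without villin-TLR4 replicate 1. Single arrays decided these calls. The erythrocyte call ended without villin-TLR4 replicate 1 (adjusted p = 0.130) and without WT replicate 3 (0.0607), where the medians were 0.61 and 0.86. The median was 1.92 without villin-TLR4 replicate 2. The stem cell call ended without villin-TLR4 replicate 1 (0.118), WT replicate 1 (0.151) or WT replicate 2 (0.0691), with medians of 0.26, 0.21 and 0.36. The clock call ended without WT replicate 1 (0.269, median 0.15), and the plasma cell call without villin-TLR4 replicate 2 (0.521) or WT replicate 2 (0.406), with medians of 0.24 each. The plasma cell median was 0.51 without villin-TLR4 replicate 1.

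**Figure D2:**
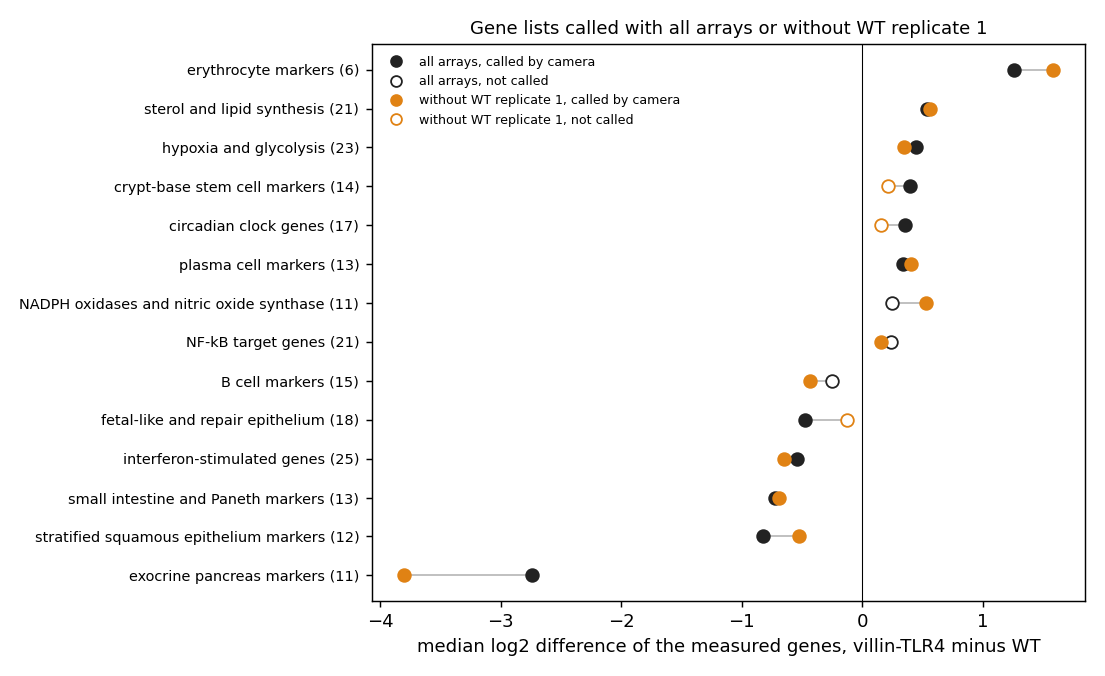
Median log2 difference, villin-TLR4 minus WT (horizontal axis), of each gene list called with all arrays or without WT replicate 1 (vertical axis, number of measured genes in brackets), in black with all arrays and in orange without WT replicate 1, filled where camera with the preset correlation called the list. Sterol and lipid synthesis lay at 0.54 and 0.56, exocrine pancreas markers at -2.74 and -3.80, and the NADPH oxidase list was called without WT replicate 1 alone.

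WT replicate 1 differed from the other WT arrays in several lists, some of them of inflammation. Relative to the mean of WT replicates 2 and 3, its median was 2.44 higher over neutrophil markers, 1.55 over cytokines, 1.45 over matrix metalloproteinases and their inhibitors and 1.25 over antimicrobial genes, and it was -1.42 over smooth muscle markers, -1.06 over xenobiotic metabolism and -1.01 over absorptive colonocyte markers. Medians there were also lower over B cell markers (-0.87), interferon-stimulated genes (-0.43) and MHC class II genes (-0.07). The NADPH oxidase and nitric oxide synthase list was 0.90 higher there. Without that array this list was called higher in villin-TLR4 colon, with a median of 0.52 and an adjusted p of 5.89e-05, against 0.25 and 0.117 with all arrays; it was also called without villin-TLR4 replicate 1 (0.49, adjusted p = 5.81e-03). Without villin-TLR4 replicate 2 its median was 0.0060 (adjusted p = 0.586) and without WT replicate 2 0.13 (0.444). Over the 18 other settings with the preset correlation its adjusted p ranged from 9.56e-09 to 0.838, and with an estimated correlation the adjusted p without WT replicate 1 was 0.855. Of its 11 members, 5 then passed adjusted over the list alone, among them Duoxa2 (4.07), Nox1 (2.93) and Nos2 (2.89). NF-kB target genes were also called without WT replicate 1, although their median then fell to 0.15 (adjusted p = 1.29e-03, and 0.855 with an estimated correlation) from 0.24 with all arrays (0.255). It was 0.35 without villin-TLR4 replicate 1 (0.0534), 0.15 without villin-TLR4 replicate 2 (0.798) and 0.09 without WT replicate 3 (0.692). Adjusted over the list alone, without WT replicate 1 there were 7 members higher and 1 lower, against 0 with all arrays. B cell markers were called lower without WT replicate 1, with a median of -0.44 and an adjusted p of 1.14e-03 (adjusted p = 0.855 with an estimated correlation), and also without villin-TLR4 replicate 2 (-0.50, adjusted p = 2.12e-03), while the median was 0.07 without villin-TLR4 replicate 1.

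The 37 lists not called with all arrays had adjusted p from 0.0574 (smooth muscle markers) to 0.929 (bile acid, ion and water transport), and medians from -0.55 (neutrophil markers) to 0.44 (smooth muscle markers). They included the TLR4 receptor complex, proliferation, Wnt targets, the epithelial cell types of the colon other than crypt-base stem cells, and the lymphoid, myeloid and stromal markers other than plasma cells. With some single array left out 20 of the 37 were called. Smooth muscle markers were then called higher without villin-TLR4 replicate 2 (0.66, adjusted p = 7.22e-03) or WT replicate 2 (0.93, 4.21e-07), with a median of -0.06 without WT replicate 1, and neutrophil markers lower without villin-TLR4 replicate 2 (-0.72, 0.0293), WT replicate 2 (-0.85, 8.34e-03) or WT replicate 3 (-1.04, 1.24e-03), with a median of 0.14 without WT replicate 1. For both lists the adjusted p with all arrays and an estimated correlation was 0.859; an estimated correlation was not used with these arrays left out. Adjusted over the list alone, 8 memberships of these lists were higher and 4 lower. These counts were 41 and 18 without WT replicate 1, 5 and 11 without WT replicate 2, 5 and 1 without villin-TLR4 replicate 1 and 0 and 0 without villin-TLR4 replicate 2. Immediate early genes held 5 of the higher ones, Atf3, Fos (1.43 ± 0.35), Jun (1.44 ± 0.33), Zfp36 (1.44 ± 0.31) and Klf4 (1.10 ± 0.27), and 1 of the lower, Fosl1, while the list had a median of 0.39 and an adjusted p of 0.107 (4.24e-04 without villin-TLR4 replicate 1 and 0.0257 without WT replicate 2). Without villin-TLR4 replicate 2 the adjusted p was 0.564, the median 0.03 and 0 members passed, and without WT replicate 3 the median was 0.16 and 1 member passed higher. Fos, Jun, Zfp36 and Klf4 were chosen after their values were seen. The other higher memberships were Slc5a8 among colonocyte markers, the eosinophil granule protein Prg2 (1.28 ± 0.28) and Atf3 in the unfolded protein response. The other lower memberships included Cd44 among Wnt targets and the MHC class I light chain B2m (-1.49 ± 0.31). The median and camera's direction differed in sign for the TLR4 complex (median 0.02, mean -0.01, camera lower) and for bile acid, ion and water transport (median 0.03, mean 0.12, camera lower), and the mean and camera differed for antioxidant defence (mean 0.0025, camera lower).

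The arrays were scanned on 3 days, and the third held both groups, as villin-TLR4 replicate 2 and WT replicate 2. The former is the male and the latter a female, so sex also differs within that day, besides genotype and DSS strength. Within that day the called lists had medians of 0.63 for sterol and lipid synthesis, 0.32 for hypoxia and glycolysis, -1.72 for exocrine pancreas, -0.49 for small intestine and Paneth, -1.05 for stratified squamous, -1.002 for interferon-stimulated, -0.29 for fetal-like and repair, 0.88 for erythrocyte, 0.17 for crypt-base stem cell and 0.66 for plasma cell and -0.00053 for clock genes; these 2 arrays are part of the full comparison too. With the scan day as a block the contrast rests on that 1 array of each group, and the calls of the fetal-like and repair (adjusted p = 0.131), erythrocyte (0.133), stem cell (0.0626) and clock lists (0.349) ended. Of single probes, 11 were then called higher and 5 lower, with 1 residual degree of freedom; Duoxa2 (4.88, adjusted p = 0.0254) and Nox1 (3.93, adjusted p = 0.0376) were among those higher.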

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

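The test of which probes were found in 1 group alone was chosen after the data were seen. Outside the gene probe classes, 3 of 3771 probes were found on both villin-TLR4 arrays and on no WT array, which no comparison had used, and 10 were found on every WT array and on neither villin-TLR4 array. The signal over background was 35 and 22 on the villin-TLR4 arrays (mean 28.5) for probe mCT001227, against 12, 28 and 13 on the WT arrays, so that the groups overlapped. It was 40 and 107 (mean 73.5) for probe mMO036335, against 19, 35 and 38, and 107 and 409 (mean 258) for probe mMO036358, against 15, 9 and 32. No explanation of these 3 probes was tested.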

How the results depend on the processing

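The settings named as added, the estimated correlation without WT replicate 1 and array weights over all kept probes, were chosen after seeing the data. Values are log2 villin-TLR4 minus WT, and the cause of a change was not tested unless said. Both counts of called probes stayed at 0 under 9 planned choices of background, normalization, source, filter and moderation. They became 18 higher and 17 lower with arrayWeights computed from probes with no spot marked bad, where WT replicate 1 had a weight of 0.141 and WT replicate 3 of 4.32, and 5 and 7 with weights over all kept probes. With the replicate number as a block they were 8 and 25, though the labels give no pairing and same-numbered arrays deviated with r of -0.15 and -0.20; with the scan day as a block they were 11 and 5. Either block leaves 1 residual degree of freedom. At an unadjusted p below 0.05 with a fold of at least 1.5 they were 409 and 361. Leaving out each array in turn gave 0 higher each time and 0 to 1 lower, the 1 without WT replicate 2. A group left with 1 array is assumed to vary like the other group. Called lists numbered 11, and 19 with median centring (which moved the median of all probes from 0.02 to 0.13), 24 with the replicate block, 18 with the scan day block, 11 to 20 with single arrays left out (17 without villin-TLR4 replicate 2, 20 without WT replicate 3), 0 with an estimated correlation, 0 with fry and 0 with the added setting, against 9 to 15 otherwise. Of the 11 lists, 3 (pancreas, sterol, hypoxia) were called the same way in all settings with the preset correlation that could test them. Among these settings, the small intestine and Paneth call ended only with the deposited table (camera adjusted p = 0.0672). The stratified squamous call ended only with arrayWeights (0.165). Of 130 named genes, 109 were called in no setting. The signal over background, lowest on WT replicate 1 at 29, limits dim probes.

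Of the values that turned direction, 129 were called in neither setting and 4 were called in the alternative, all with the scan day block: T cell 0.33, smooth muscle -0.68, enteric neuron and glia -0.37 and adipocyte -0.40. The lowest correlation between arrays became -0.80 with the deposited table, by its division per probe. With the scan day block the others were Cd4 0.18, Ly96 0.14, Lcn2 0.48, Hoxa10 0.070, Klrd1 0.040, Itgae 0.48, Smtn -0.59, Actg2 -0.24, antioxidant 0.20, TLR4 complex -0.038, cytokines 0.11, chemokines 0.036, antimicrobial 0.19, MHC class II 0.17, Wnt 0.21, tuft 0.17, posterior Hox 0.057, NK 0.38, macrophage 0.17, neutrophil 0.18, endothelial 0.054, junction -0.27, oxidative phosphorylation 0.10 and bile acid -0.15. With arrayWeights they were Ly96 0.00051, Lcn2 0.18, antioxidant 0.012, TLR4 complex -0.0014, cytokines 0.34, chemokines 0.054, proliferation -0.12, colonocyte -0.053, goblet -0.37, T cell -0.11, macrophage 0.35, neutrophil 0.19, mast cell 0.034, fibroblast -0.0090, neuron and glia -0.12, metalloproteinases 0.17, xenobiotic -0.040, fatty acid oxidation -0.17 and unfolded protein -0.078. With the replicate block they were Tlr4 -0.094, Reg3b -0.25, Il1b -0.69, tuft 0.20, posterior Hox 0.070, B cell -0.13 and bile acid 0.15. Neuron and glia came to -0.15 with cyclic loess and -0.0034 with median centring, which also gave Lgr5 0.0084, Itgae 0.029 and TLR4 complex 0.28. Cytokines and bile acid came to 0.038 and 0.054 with the deposited table, and to 0.057 and 0.035, with chemokines -0.20, on probes found on all 5 arrays. The TLR4 complex came to -0.0037 with the mean of a gene's probes. Where a list's printed sign did not turn, camera's direction did.

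With single arrays left out, values that turned ranged over -0.26 to 0.066 for Cd4, -0.36 to 0.060 for Itgae, -0.18 to 0.34 for Tlr4, -1.16 to 2.32 for Reg3b, -0.17 to 3.20 for Reg3g, -0.69 to 1.79 for Il1b, -0.22 to 0.15 for Lgr5, -0.77 to 0.089 for Ly96 and -1.03 to 0.18 for Lcn2. Lists ranged over -0.035 to 0.15 (antioxidant), -0.48 to 0.090 (chemokines), -0.66 to 0.10 (MHC class II), -0.29 to 0.20 (tuft), -0.11 to 0.41 (posterior Hox), -0.32 to 0.075 (T cell), -0.32 to 0.20 (NK), -0.50 to 0.065 (B cell), -0.39 to 0.18 (macrophage), -0.25 to 0.29 (neuron and glia), -0.56 to 0.75 (adipocyte), -0.11 to 0.19 (bile acid), 0.025 to 0.19 (proliferation), 0.046 to 0.47 (enteroendocrine), -0.13 to 0.34 (unfolded protein), -0.041 to 0.039 (TLR4 complex), -0.66 to 0.22 (cytokines), -0.60 to 0.18 (antimicrobial), 0.012 to 0.58 (colonocyte), -1.04 to 0.14 (neutrophil), -0.69 to -0.18 (mast cell), -0.063 to 0.93 (smooth muscle), -0.098 to 0.22 (junction), -0.87 to -0.027 (metalloproteinases), -0.11 to 0.32 (fatty acid oxidation) and 0.013 to 0.48 (goblet). Without WT replicate 1 and with an estimated correlation, an added setting, they were antioxidant 0.15, TLR4 complex 0.035, cytokines 0.22, chemokines 0.090, antimicrobial 0.18, colonocyte 0.012, T cell -0.088, macrophage 0.18, neutrophil 0.14, mast cell -0.18, smooth muscle -0.063, neuron and glia -0.25, junction -0.098, metalloproteinases -0.027, fatty acid oxidation -0.11 and unfolded protein -0.039.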

Other observations

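The tests of explanations in this part were chosen after the result was seen, except for the count over the splits of the arrays, whose outcome had not been seen.

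Members of the lists that were not called gave further values, not called changes. The heme oxygenase Hmox1 and the sulfiredoxin Srxn1, both of antioxidant defence, differed by -1.91 ± 0.47 and -0.81 ± 0.31. Among TLR4 adaptors, Myd88 differed by -1.02 ± 0.32 and Irak2 by 0.77 ± 0.27. The EGFR ligand Areg and the lymphotoxin Ltb differed by 1.303 ± 0.69 and -0.58 ± 0.24, the monocyte chemokine Ccl7 by -2.95 ± 0.95 and the stromal chemokine Cxcl12 by 1.596 ± 0.54; the 4 kept probes of Cxcl12 ranged from -0.05 to 1.596. Of the goblet cell genes, the trefoil factor Tff3 differed by 0.82 ± 0.34 and the ribonuclease Ang4 by -2.98 ± 1.48, and the replication enzymes Rrm1 and Top2a by 0.47 ± 0.23 and 0.94 ± 0.47. The Hox genes Hoxa13, Hoxa10 and Hoxb6 differed by 0.58 ± 0.32, -0.39 ± 0.28 and 0.43 ± 0.23 (log2 ± SE, n = 2 and n = 3). Hoxd4, marked found on 0 of 3 WT arrays, was at least 1.84-fold higher. The other kept probe of Hoxa10 differed by -1.27. Leaving out 1 array moved some of these by over 1.5 times: without WT replicate 1 Top2a came to 0.52, Hoxa13 to 0.32, Tff3 to 0.54, Ccl7 to -1.95 and Cxcl12 to 1.05; without WT replicate 3 Ang4 came to -1.46, Areg to 0.82 and Hoxa10 to -0.25; without WT replicate 2 Hoxa10 came to -0.59; and without villin-TLR4 replicate 2 Areg came to 0.67. Limma's adjusted p with all arrays was at least 0.882 for each of these genes.

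Pancreatic enzyme genes were brighter on the WT arrays. Scan day as the whole cause was not excluded: on the day that held both groups the median was -1.72, but from 1 array of each group. WT replicates 1 and 3, of another day, differed by 5.15 in the median. Pancreatic tissue taken along with some WT pieces is a candidate explanation that stays open: between WT replicates 3 and 2, alike in genotype and DSS, the median differed by 3.31, but this spread raised the explanation and cannot test it. Whether such tissue also brought Apoa1, Apoa4 and Apoc3 is open as well. These genes lay on average 1.02 higher on WT replicate 1 than on WT replicate 2, where the pancreatic median lay at -1.20, and 1.59 higher on WT replicate 3 than on WT replicate 2, in the direction of the pancreatic genes. An effect of genotype or of DSS strength on these genes was not tested apart from this.

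WT replicate 1 stood apart from the other arrays. Scatter of dim probes alone was argued against, as far as brightness is the normalized mean over all arrays. Over the brightest 4546 probes its differences to WT replicates 2 and 3 had SDs of 0.967 and 0.926. These were at least 1.85 times the 0.5005 between those 2 arrays. A weak signal of the whole array was not excluded. The upper quartile of signal over background was 116 on WT replicate 1, against 252.25 to 480 on the others. Such probes can therefore still be dim on that array. More neutrophils in that piece of tissue may be part of the difference, but the neutrophil median of 2.44 raised this explanation and cannot test it. The labels give no inflammation score, so whether the mouse or the place of sampling differed was not tested. This array also had 1046 gene spots marked bad, against 0 to 4 on the others, and the quality of its RNA or hybridisation was not tested.

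Against WT replicates 2 and 3 alone, the NADPH oxidase and NF-kB lists had medians of 0.52 and 0.15 on the villin-TLR4 arrays, with 3 of 11 and 6 of 21 members lower, and neither was called with an estimated correlation (adjusted p = 0.855 for both). Scan day as the whole cause was not excluded: on the day that held both groups the median of the NADPH oxidase list was 0.87, but from 1 array of each group. DSS strength and genotype cannot be told apart, because 0 strengths were given to both groups. Sex as the whole cause was not excluded, since the comparison among females rests on 1 villin-TLR4 array. There the median over both lists was 0.24 above WT replicates 2 and 3, and no other female villin-TLR4 array was at hand to repeat it. The NADPH oxidase median was 0.28 on this array and 0.77 on the male array, and the NF-kB median 0.22 and 0.31. Against all WT arrays and without the male array, the medians were 0.0060 and 0.15. A response to the transgene is a hypothesis that these values leave open, and WT replicate 1, where the NADPH oxidase list lay 0.90 above the other WT arrays, shows that WT tissue can reach such levels.

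Over the 10 splits of the 5 arrays into 2 and 3, the real one included, 10 called at least as many lists as the real split. The real split called 11 and the highest other 25. No other split called fewer lists than the real one, so the number of called lists does not set the genotypes apart from other groupings of these arrays. The splits were in any case too few for a share below 0.05.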
